A study of Homo sapiens with 36 samples.

How the data were processed

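The series profiled total RNA from trabecular meshwork, the porous tissue through which aqueous humour leaves the eye, of people with primary open-angle glaucoma (POAG) and of control eye donors. There were 36 bead arrays, 17 from POAG and 19 from control tissue. RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I treatment, checked on a Bioanalyser and made into biotinylated cRNA with an Ambion MessageAmp kit, per the labels' protocols. POAG tissue was collected at surgery and control tissue from donated eyes, per the labels, so disease and way of collection are the same split. The series design states 13 control individuals, 6 of them with both eyes measured, and 15 individuals with POAG. The labels do not say which POAG arrays share an individual.

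The deposited intensity values were linear bead summaries for 47293 probes, with no normalization between arrays. The deposited detection p-value of each probe on each array stood beside its intensity. Scanner software, background setting and bead summary were not given in the sources used here. The authors' value table held log2 values. Recomputing it showed quantile-normalized log2 intensity with no background correction, with a largest absolute difference of 4.992e-09 and a median of 6.73 in each column. The submitters' processing notes list limma without a version or a role.

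Probes were named from the platform annotation, updated through gene identifiers with the RefSeq gene table of assembly GRCh38.p14, which was used for names only. Of the probes, 18468 named 1 gene, 0 named several and 28825 were unnamed here. That table matched the gene identifier of 18451 probes. Probes without a name were not used in the tests.

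Intensities were processed in R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. The neqc function corrected background by a normal-exponential model with background mean and SD inferred from the detection p-values, added an offset of 16, quantile normalized and took log2. A probe was kept when its detection p was under 0.05 on at least 9 of the 36 arrays, which 13252 probes met. For a gene with several kept probes the one with the highest mean was used. XIST and Y-linked genes were left out. This left 9186 genes. Of the 272 genes with several kept probes, 56 passed the threshold, and 2 of those had another probe of opposite sign at an unadjusted p under 0.05. Probes detected per array ranged from 8407 to 13585 in POAG and from 7310 to 12472 in control tissue. The number of arrays limits the precision.

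The 19 control arrays were averaged to 13 donor profiles through a shared label of the interval between death and collection, and the 17 POAG arrays entered as they were. POAG p-values therefore treat 17 arrays as separate although they come from 15 individuals. Groups were compared with limma's lmFit and eBayes, and a gene passed the threshold at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are POAG minus control on the log2 scale, with the standard error of the moderated fit. A probe detected on no array of a group has only a bound there. Its fold was computed from the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal.

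Sets of marker and pathway genes (34 lists) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. The fry test was run as an alternative. A list needed at least 3 tested members, which 33 lists had. Of these, 1 list enters the counts of lists but its own result is not reported here. The lens marker list had 2 of 11 members tested and was not tested. Camera sets a list against all other genes, whereas fry asks whether a list's own genes move.

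Both eyes of a donor were compared by the correlation of their deviations from the control mean over tested genes, against every pairing of the same 12 arrays. The interval between death and collection was examined within the 13 control donors as a limma slope, with 100 permutations. Single intervals are not reported. Permutation tests of single values were 2-sided and used 100000 resamples or full enumeration, except that list means were set against the interval with 10000 permutations per list.

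Array identifiers in the file headers placed the arrays on 6 chips, numbered 1 to 6 here. Chip 1 held 4 POAG and 2 control arrays and chip 4 held 1 POAG and 5 control arrays. Chips 2 and 3 held 6 control arrays each, and chips 5 and 6 held 6 POAG arrays each. Chip was fitted as a fixed block and as a random block on the 36 arrays as separate samples, and the groups were also compared within chips 1 and 4.

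Alternatives changed the background correction, the normalization between arrays, the filter on dim probes, the choice of probe, the averaging of arrays, the samples entered, the array weights, the block and the list test. They included the authors' values, normexp with an offset of 50, a filter of 18 arrays, and each of the 30 profiles left out in turn. The groups, the tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 largest changes in each direction past the threshold and at least 1.5-fold, up to 4 members of each list with the smallest p, and any tested member of the glaucoma list. Genes outside it are said to have been chosen after their values were seen.

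The gene test was tested on simulated data for the comparison of POAG with control, over 9186 genes and 30 profiles, with 200 genes changed in each of 10 draws. It recovered 41% of genes changed by 1.5-fold, 84.6% at 2-fold, 99.6% at 4-fold and 100% at 8-fold. False calls made up 6.07% of all calls. In 20 draws with no change, limma called 0 genes. The simulation drew genes independently and held no chip effect.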

Results

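Gene expression was measured on bead arrays in trabecular meshwork from POAG, a disease of the optic nerve in which drainage of aqueous humour is often impaired, and from control eyes. There were 17 POAG arrays and 19 control arrays, the latter averaged to 13 donor profiles. Unless stated otherwise, n = 17 for POAG and n = 13 for control. Fits with chip as a block used all 36 arrays as separate samples, with both eyes of 6 control donors entered separately, and fits within chip 1 or 4 used its 6 arrays. Where a chip block is named without its kind, it is the fixed block. The median number of probes detected per array was 11613 in POAG and 10694 in control tissue. All POAG tissue came from surgery and all control tissue from donated eyes, so no comparison here separates disease from way of collection.

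The series asked which genes differ between POAG and control tissue across the genome. Haemoglobin genes rose most in POAG, led by HBA2 with a log2 fold change of 6.05 ± 0.44 (SE). Next to them stood MGP, an inhibitor of calcification abundant in trabecular meshwork, at 2.63 ± 0.35, and the antigen-presenting gene HLA-DPA1 at 2.46 ± 0.36. The calls of both ended with chip as a fixed block, where MGP stood at 0.98 ± 0.91 (adjusted p = 0.691; 0.27 within chip 4) and HLA-DPA1 at 2.09 ± 0.63 (adjusted p = 0.0826). Epithelial genes fell most, led by CALML3, a calmodulin-like gene of stratified epithelium, at -5.37 ± 0.54, and the keratin gene KRT19 at -5.07 ± 0.58, which lost its call with the block (-4.04 ± 1.23, adjusted p = 0.0863). Of 9186 genes, 1642 (17.9%) passed the threshold, 1010 higher and 632 lower in POAG. At a fold change of at least 1.5, 762 were higher and 492 lower.

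The split between higher and lower genes moved with the scaling between arrays. Genes higher made up 61.5% of calls with quantile normalization, 97.1% with median scaling (4143 higher, 122 lower) and 45.6% with cyclic loess (550 higher, 656 lower). The median log2 fold change of all genes was 0.09, 0.68 and 0.02 under these, so directions are relative to the scaling. From the 36 arrays as separate samples, without a chip term, limma called 1508 genes. With chip as a fixed block 123 genes passed, 62 higher and 61 lower, of which 74 were among the 1642, and 87.6% of the 1642 had the same sign. Within chip 1 alone limma called 6 genes, within chip 4 alone 66, and with chip as a random block 589.

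Other genes with large increases were ECRG4 (2.32 ± 0.29), FCGBP (2.28 ± 0.36), CYTL1 (2.24 ± 0.41) and CELF5 (2.13 ± 0.47). Other genes with large decreases were the iron-binding LCN2 (-4.20 ± 0.52), the eye transcription factor gene PAX6 (-4.06 ± 0.56), the calcium-binding S100A9 (-3.80 ± 0.55) and TGM1, a cross-linking enzyme of stratified epithelium (-3.62 ± 0.50). TNNT3 stood at -3.51 and FAM3D at -3.46. The calls of these 10 genes ended with chip as a fixed block, where the fold changes were 1.40 ± 0.55, 2.45 ± 0.74, 2.10 ± 0.79 and 2.32 ± 0.87 for the 4 higher genes, and -3.95 ± 1.14, -3.93 ± 1.16, -2.60 ± 1.18, -3.50 ± 1.07, -2.29 ± 0.73 and -2.99 ± 1.03 for the 6 lower genes, in the same order. Of all 80 named genes that passed, 14 passed with the block and 79 kept their sign, 65 of them at 0.5 times the fold change or more. Their median SE went from 0.318 to 0.591, since only chips 1 and 4, with 12 arrays, hold both groups. Most named genes were chosen by size or p in a fit that includes those 12 arrays, which favours a kept sign. Of all 1642 genes that passed, 87.6% kept it. With chip as a random block, which also uses comparisons across chips, 14 of 84 genes named in the text lost their call.

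Red blood cell markers rose together. Of 6 tested members 5 were higher and 0 lower, and 6 were higher when adjusted over the list alone. The median log2 fold change was 5.25 (camera adjusted p = 9.9e-14; adjusted p = 0.0033 with an estimated correlation). The haemoglobin genes HBB and HBD rose by 5.40 ± 0.34 and 5.09 ± 0.29. HBA1 and HBA2, at 5.92 and 6.05, are near-identical copies whose signals cannot be assigned with certainty, and the same holds for the fetal genes HBG1 and HBG2, at 2.46 and 2.50. The fetal genes lost the call with chip as a block, at 0.57 ± 0.81 (adjusted p = 0.83) and 0.35 ± 0.77 (adjusted p = 0.902), whereas HBA1, HBA2, HBB and HBD kept it. ALAS2, the haem synthesis enzyme of red cell precursors, chosen after its values were seen, rose by 1.00 ± 0.20, and lost its call with chip as a block (0.66 ± 0.35, adjusted p = 0.389). The list mean was 10.4 ± 0.796 (SD) in POAG and 6.37 ± 0.629 in control profiles, and every POAG profile (lowest 8.93) lay above every control profile (highest 8.14). The list median was 4.89 with chip as a block, 4.50 within chip 1 and 5.51 within chip 4.

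Markers of corneal and conjunctival epithelium fell together. Of 12 tested members 10 were lower and 0 higher, and 12 were lower when adjusted over the list alone. The median was -2.39 (camera adjusted p = 9.26e-16; adjusted p = 0.0456 with an estimated correlation). Among the keratin genes of stratified epithelium, KRT13 fell by 4.62, KRT14 fell by 3.76 and KRT5 fell by 3.73. KRT15 was detected on 0 of 17 POAG arrays and 16 of 19 control arrays, and was at least 21.1-fold lower in POAG (adjusted p = 5.57e-06). The calls of these 4 keratin genes ended with chip as a block, where KRT13 stood at -4.20, KRT14 at -2.32 and KRT5 at -2.97. The list mean was 5.59 ± 0.315 (SD) in POAG and 8.42 ± 1.72 in control profiles, where it ranged from 5.47 to 10.6. The list median was -2.39 with chip as a block (adjusted p = 6.23e-06), -1.90 within chip 1 and -2.91 within chip 4, where the call was lost (adjusted p = 0.133).

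**Figure D1:**
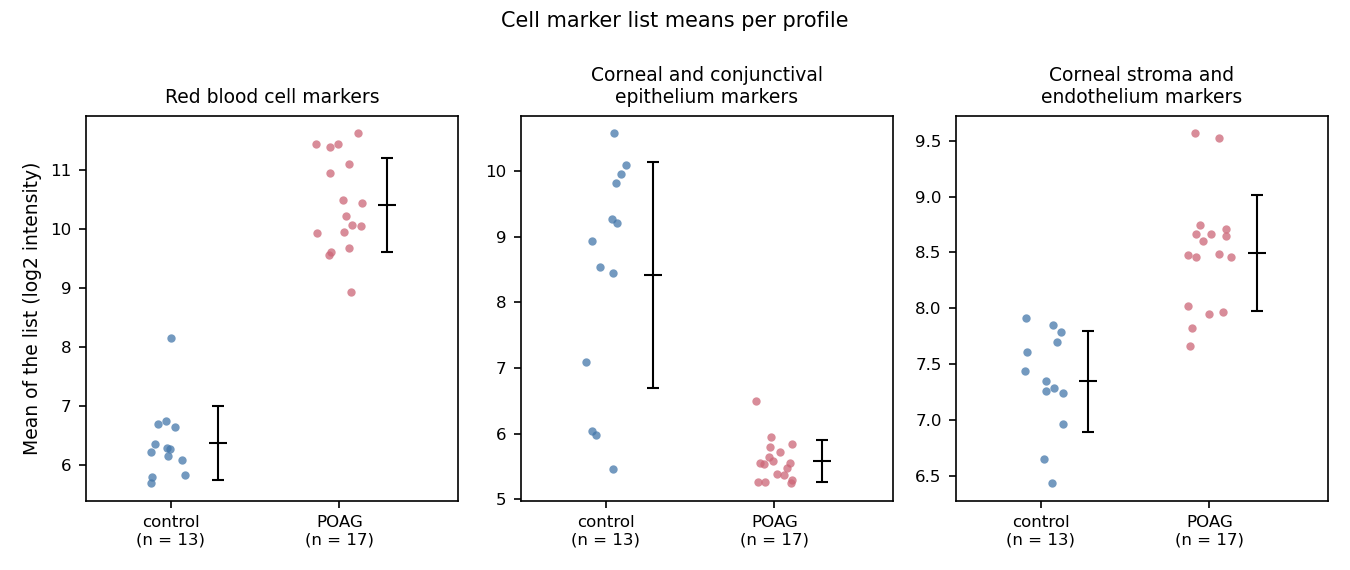
Means of the red blood cell, surface epithelium, and corneal stroma and endothelium marker lists (log2 intensity, vertical axes) in 13 control donor profiles and 17 POAG arrays, with each point 1 profile and bars giving mean ± SD. Red blood cell means were 8.93 or higher in POAG and 8.14 or lower in control profiles, and epithelium means spread from 5.47 to 10.6 in control profiles.

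Markers of corneal stroma and endothelium rose, with 6 of 9 tested members higher and 0 lower, also when adjusted over the list alone. LUM, a keratan sulfate proteoglycan of the corneal stroma, rose by 1.99 ± 0.35, COL8A2, a collagen of the endothelial basement membrane, by 1.96 ± 0.32, PTGDS, a prostaglandin D synthase, by 1.75 ± 0.27, and the sulfotransferase gene CHST6 by 1.42 ± 0.25. These 4 calls ended with chip as a block, at 1.62 ± 0.58, 1.43 ± 0.61, 1.39 ± 0.54 and 1.60 ± 0.45. The median was 1.42 (camera adjusted p = 0.000382; adjusted p = 0.134 with an estimated correlation). The median was 1.39 with chip as a block, within chip 1 it was 0.64 and the call was lost (adjusted p = 0.127), and within chip 4 it was 2.01. Surface epithelium markers, at a median of -2.39, moved the other way in the same tissue.

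Collagen and structural matrix genes rose in POAG relative to other genes. Of 25 tested members 12 were higher and 0 lower, with 13 higher when adjusted over the list alone. Fibronectin (FN1) rose by 1.88 ± 0.26, the collagen-binding proteoglycan gene FMOD by 1.91 ± 0.31, and the fibrillar collagen genes COL5A2 and COL1A2 by 1.61 ± 0.28 and 1.33 ± 0.25. Of these, COL5A2 passed with chip as a block (1.93), whereas FN1 (0.79), FMOD (0.71) and COL1A2 (0.70) lost the call. The median was 0.65 (camera adjusted p = 0.000602; adjusted p = 0.454 with an estimated correlation). The call was lost with chip as a fixed block (median 0.02, adjusted p = 0.592), within chip 1 (median 0.29) and within chip 4 (median -0.18). With chip as a random block it held (median 0.45, adjusted p = 0.00351). The call was also lost with the surface epithelium mean as a covariate (median 0.07, adjusted p = 0.798).

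Macrophage and myeloid markers rose, with 8 of 12 tested members higher and 0 lower, and 9 higher when adjusted over the list alone. TYROBP, an adaptor of immune receptors, rose by 1.69 ± 0.40, AIF1, a macrophage calcium-binding gene, by 1.54 ± 0.36, and CD14, a receptor for bacterial lipopolysaccharide, by 1.06 ± 0.25. These 3 calls ended with chip as a block, at 0.91 (adjusted p = 0.598), 1.05 (adjusted p = 0.40) and 0.24 (adjusted p = 0.882), and all were negative within chip 4. The median was 1.01 (camera adjusted p = 0.000382; adjusted p = 0.454 with an estimated correlation). The median was 0.63 with chip as a block (adjusted p = 0.035), within chip 1 it was 1.55, and within chip 4, with 1 POAG array, it turned to -0.70. Red blood cell markers, at a median of 5.25, rose in the same tissue.

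Antigen presentation genes rose, with 7 of 14 tested members higher and 0 lower, and 9 higher and 1 lower when adjusted over the list alone. Among those higher were the class II genes CD74, the invariant chain, at 1.51 ± 0.31, HLA-DMB at 1.11 ± 0.30 and HLA-DRA at 0.80 ± 0.18. Of these, HLA-DMB passed with chip as a block (2.77), whereas CD74 (1.34) and HLA-DRA (1.02) lost the call. The median was 0.68 (camera adjusted p = 0.00456; adjusted p = 0.528 with an estimated correlation), and it was 0.58 with chip as a block, 0.91 within chip 1 and -0.14 within chip 4. Interferon-stimulated genes also rose, with 6 of 16 higher and 1 lower, also when adjusted over the list alone. IFI44L rose by 1.65 ± 0.22, IFIT2 by 1.54 ± 0.27 and IFIT1 by 1.32 ± 0.16. The lower gene, IRF1, chosen after its values were seen, stood at -0.75, at 0.28 with median scaling, at -0.40 with chip as a block (adjusted p = 0.682) and at 0.39 within chip 1. With the block IFIT1 passed (1.23), whereas IFI44L (1.16) and IFIT2 (1.11) lost the call. The median was 0.48 (camera adjusted p = 0.0129; adjusted p = 0.454 with an estimated correlation), and it was 0.36 with chip as a block, 0.75 within chip 1 and -0.14 within chip 4. Myeloid markers, at a median of 1.01, moved with both lists, at 1.55 within chip 1 and -0.70 within chip 4. The interferon call was lost without the 4 POAG arrays whose interval label has another form (adjusted p = 0.111).

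Wnt pathway genes rose, with 4 of 11 tested members higher and 0 lower, and 5 higher when adjusted over the list alone. The members past the threshold were FZD1, a Wnt receptor (1.26 ± 0.22), and 3 genes of secreted proteins, DKK3 (1.20 ± 0.22), SFRP2 (0.95 ± 0.27) and FRZB (1.30 ± 0.37). All 4 calls ended with chip as a block, where FZD1 stood at 0.92 (adjusted p = 0.204), DKK3 at 0.44 (adjusted p = 0.637), SFRP2 at 0.17 (adjusted p = 0.929) and FRZB at -0.066 (adjusted p = 0.983). DKK3, SFRP2 and FRZB were negative within chip 4. The median was 0.66 (camera adjusted p = 0.00376; adjusted p = 0.184 with an estimated correlation). The call was lost with chip as a fixed block (median 0.17, adjusted p = 0.227) and within chip 4 (median -0.46), and the median within chip 1 was 0.80. With chip as a random block it held (median 0.57, adjusted p = 0.00231). With the surface epithelium mean as a covariate the call was also lost (median 0.24, adjusted p = 0.33).

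Glucocorticoid response genes fell relative to other genes, with 3 of 11 tested members lower and 0 higher, and 4 lower when adjusted over the list alone. CEBPD, a transcription factor gene of the acute phase response, fell by 2.21 on the log2 scale, and SERPINA3, a protease inhibitor gene, fell by 1.36. KLF9, a Krüppel-like factor gene, stood at -0.81, and at 0.37 with median scaling. With the block CEBPD passed (-2.94), whereas SERPINA3 (-2.30) and KLF9 (-1.77) lost the call. The median was -0.23 (camera adjusted p = 0.00601; adjusted p = 0.454 with an estimated correlation), and 0.49 with median scaling, where the list was still lower relative to other genes (adjusted p = 0.0263). The glucocorticoid median was -1.37 with chip as a block, within chip 1 it was -1.80 and within chip 4 it was -1.18, and the call was lost without the 4 POAG arrays of another label form (adjusted p = 0.074). Immediate early genes, which respond to stimuli within minutes, stood just over the list threshold (median -0.16, camera adjusted p = 0.0508; adjusted p = 0.662 with an estimated correlation). They passed as lower in 13 of 24 other settings, among them cyclic loess (adjusted p = 0.00845) and median scaling (adjusted p = 0.0222), where the median was 0.31 but still low relative to other genes. They also passed in 12 of 30 fits with 1 profile left out (adjusted p from 0.00706 to 0.143 over the 30), namely without control donor 3, 7, 8, 10, 11 or 12 or POAG array 7, 9, 10, 11, 12 or 17. Of 14 members 4 were lower and 0 higher, with 5 lower when adjusted over the list alone, among them the mRNA decay gene ZFP36 (-1.78 ± 0.34), the phosphatase gene DUSP1 (-1.63 ± 0.37) and GADD45B (-1.19 ± 0.29), all of which passed with chip as a block. The immediate early list passed with chip as a block (median -0.77, adjusted p = 6.23e-06), and its medians were -0.71 within chip 1 and -0.96 within chip 4. With the surface epithelium mean as a covariate it did not pass (median 0.14, adjusted p = 0.876). There the calls of ZFP36 (-1.26), DUSP1 (-1.76) and GADD45B (-1.20) ended.

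**Figure D2:**
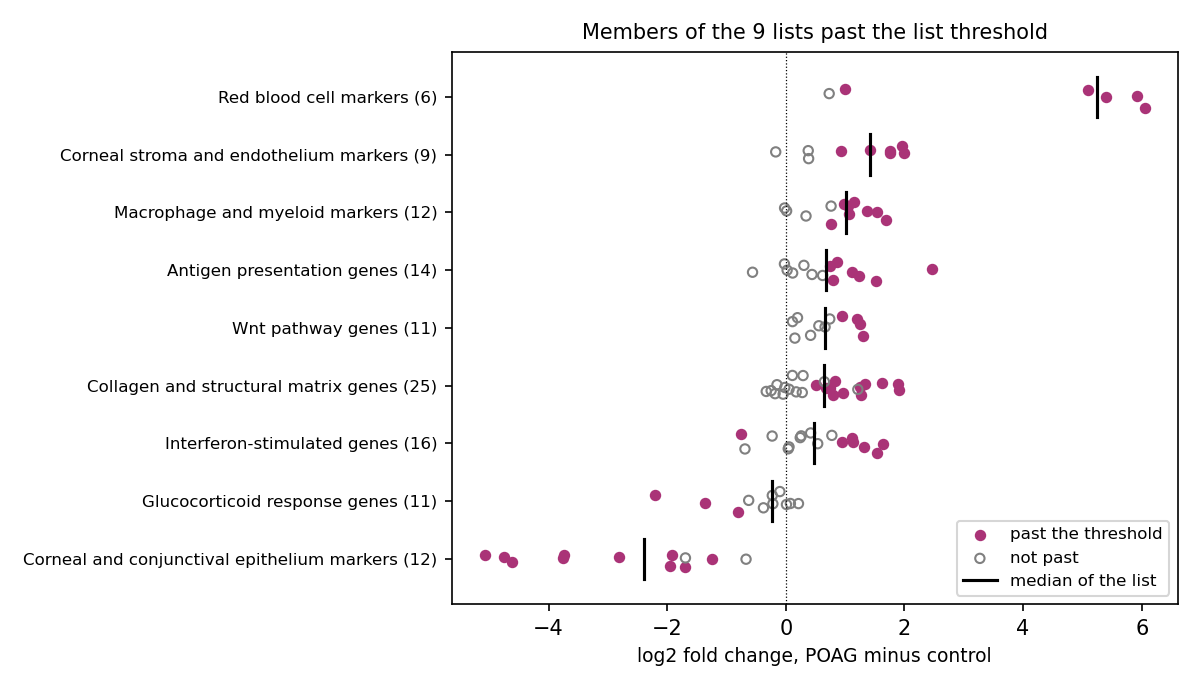
Log2 fold changes, POAG minus control (horizontal axis), of the tested members of the 9 lists past the list threshold, with the number of members in brackets, filled points for genes past the threshold, open points for the others and a bar at the list median. Medians ran from -2.39 for surface epithelium to 5.25 for red blood cell markers, and the glucocorticoid median of -0.23 was 0.49 with median scaling.

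Trabecular meshwork markers had 3 of 15 members higher and 0 lower, also when adjusted over the list alone, with a median of 0.48, and did not pass as a list, except without a filter on dim probes and with fry (camera adjusted p = 0.112; median -0.28 with chip as a block, -0.05 within chip 1 and -0.54 within chip 4). MGP and AQP1, a water channel gene (0.93 ± 0.29; 1.62 ± 0.48 with chip as a block, where its call ended), were among those higher. Among genes linked to POAG by family or association studies, 17 were tested, 2 higher and 2 lower, also when adjusted over the list alone. TEK, the angiopoietin receptor gene, rose by 0.80 ± 0.20 and GMDS, a fucose synthesis gene, by 0.84 ± 0.24. ABCA1, a cholesterol exporter gene, stood at -0.72 ± 0.17, and at 0.35 with median scaling. CDKN2B, a cell cycle inhibitor gene, stood at -1.21 ± 0.38, and lost its call without control donor 11 (-1.08, adjusted p = 0.052). These 4 calls ended with chip as a block, where TEK stood at 0.36 (adjusted p = 0.687), GMDS at 0.011 (adjusted p = 0.996), ABCA1 at -0.89 (adjusted p = 0.113) and CDKN2B at -0.77 (adjusted p = 0.714). TEK and GMDS were negative within chip 4, and CDKN2B was at 0.26 within chip 1 and at 0.83 with the surface epithelium mean as a covariate. MYOC, the gene of myocilin, was detected on every array but did not pass (0.76 ± 0.36, adjusted p = 0.144). MYOC stood at -0.52 with chip as a block (adjusted p = 0.785), -1.74 within chip 4 and -0.44 with the epithelium covariate. OPTN (0.34, adjusted p = 0.142; -0.072 within chip 4) and CYP1B1 (-0.48, adjusted p = 0.165; 0.42 with median scaling) did not pass either. The list's median was 0.19 (camera adjusted p = 0.95), and it was -0.48 with chip as a block (adjusted p = 0.0233), -0.35 within chip 1 and -0.46 within chip 4.

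**Figure D3:**
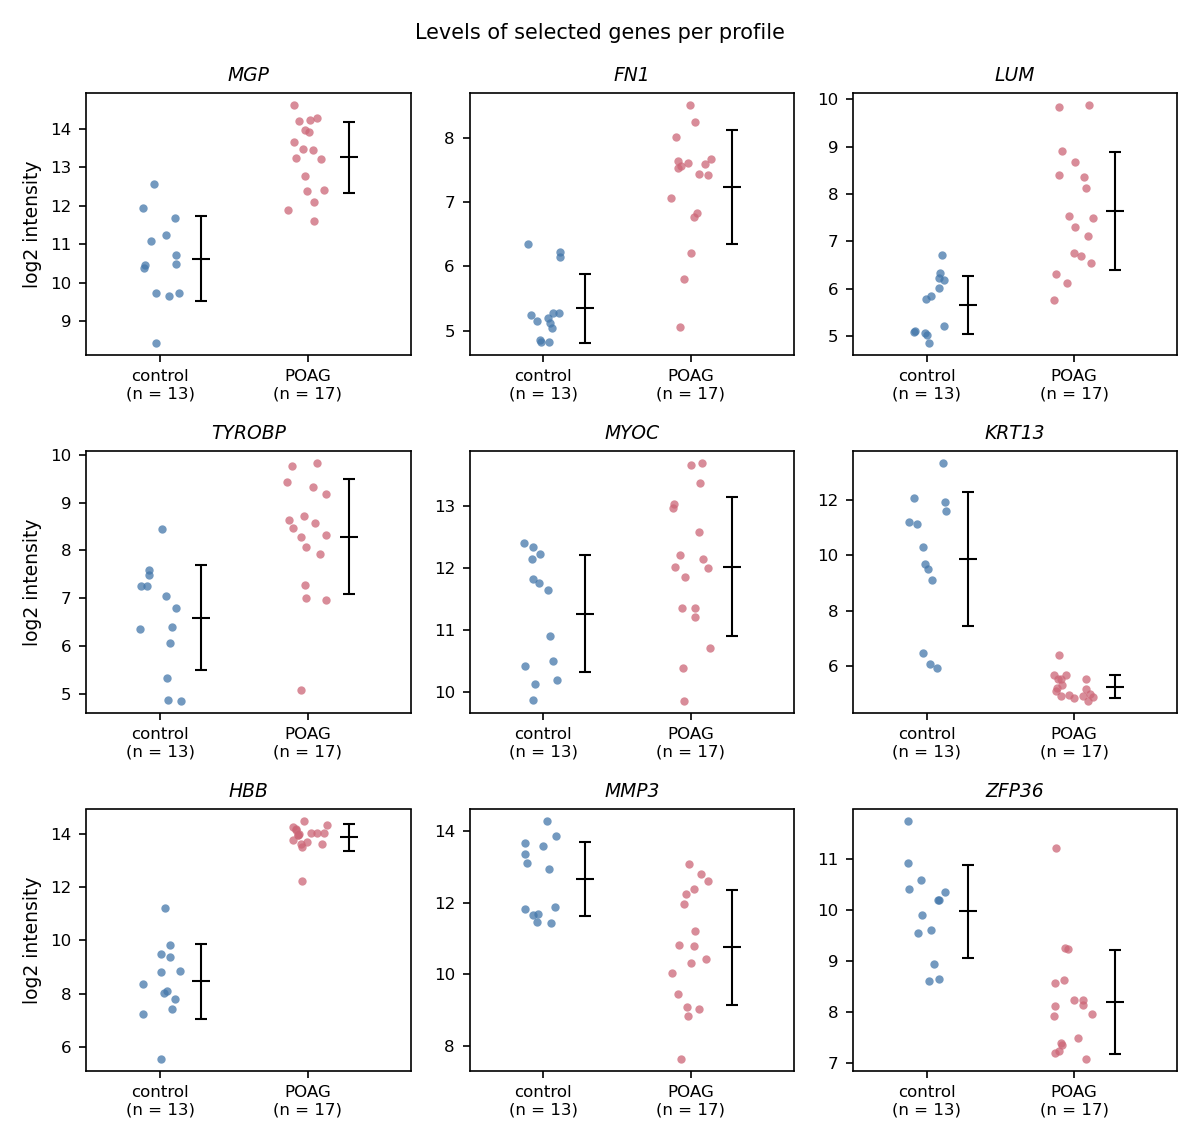
Log2 intensity (vertical axes) of MGP, FN1, LUM, TYROBP, MYOC, KRT13, HBB, MMP3 and ZFP36 in 13 control donor profiles and 17 POAG arrays, with each point 1 profile and bars giving mean ± SD. HBB averaged 13.9 in POAG and 8.47 in control profiles, whereas MYOC averaged 12.0 and 11.3, did not pass the threshold and turned to -0.52 with chip as a block.

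Of 33 lists tested 9 passed with the preset correlation, 7 higher and 2 lower. The calls for red blood cell and surface epithelium markers, 2 lists, held with an estimated correlation. With chip as a fixed block 14 lists passed, and with chip as a random block 11. The fry test called 10 lists in 1 direction and 20 in either direction.

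The control donors with both eyes measured give the error behind a profile. Over 6 donors the correlation of both eyes' deviations from the control mean averaged 0.403 (range -0.00935 to 0.659), a correlation across genes, which are not independent replicates. Arrays of different donors averaged -0.0157. The exact p over all 10395 pairings of the 12 arrays was 1e-04, the smallest these pairings can give, and 9 of 12 arrays were closest to their own donor's other array. The lowest value belonged to the donor of control array 8, and without that donor the mean was 0.486 (exact p = 0.00106, n = 5). The median SD of a gene was 0.388 between eyes and 0.214 between donors, both with the donor of array 8 included. The value between donors is a variance component, with the variance between eyes taken out and negative values set to 0. It is therefore not the observed spread of donors. Of these 6 donors 0 had both arrays on the same chip, so the SD between eyes includes differences between chips, and other pairings can join arrays of the same chip.

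Among 13 control donors, expression was set against the interval between death and collection. Limma called 0 genes, with 319 at an unadjusted p under 0.05, and 66 of 100 permutations of the intervals gave as many (median 392). Of 33 lists 0 passed, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.504 in a permutation test of the list means.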

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

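The groups' comparison within single chips, chip as a random block, the epithelium covariate and the fits without control array 8 were chosen after seeing the data; the other alternatives were set before. For the counts of genes, most alternatives of background, filter, probe, averaging and samples stayed within 1.5 times of the 1642 genes. So did each profile left out in turn (1386 to 1926 genes, with 825 to 1227 higher, 548 to 699 lower, and 9 to 11 lists). With the 2 most correlated pairs of POAG arrays averaged, which left 15 case profiles, 1324 genes passed, 794 higher and 530 lower. Counts of genes at least 1.5-fold fell to 309 higher and 309 lower with the authors' values. Without background correction they were the same, because the authors' values hold none. These 2 alternatives are counted separately here but are in effect 1 setting. With an offset of 50 the count fell to 425 higher. The lack of correction and this offset both compress low signals by construction. Median scaling gave 4265 genes, 4143 higher and 122 lower, with 3799 and 113 at least 1.5-fold. Cyclic loess gave 550 higher, 354 of them at least 1.5-fold. Chip as a fixed block gave 123 genes, 62 higher and 61 lower, all at least 1.5-fold, and 14 lists. Chip 1 alone gave 6 genes (1 higher, 5 lower) and chip 4 alone 66 (30 higher, 36 lower), all at least 1.5-fold, from 6 arrays each. Chip as a random block gave 589 genes, 325 higher and 264 lower, with 290 and 252 at least 1.5-fold. The epithelium covariate gave 163 genes, 74 higher and 89 lower, all at least 1.5-fold. An estimated correlation left 2 lists. Apart from the compression of low signals, the cause of these changes was not tested.

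Of the lists, the red blood cell call held in all 24 other alternatives and no list call was lost when 1 profile was left out. Among the results reported here that passed the threshold in either fit, those whose tested direction reversed under median scaling were IRF1 0.28, KLF9 0.37 and ABCA1 0.35. With chip as a fixed block FRZB stood at -0.066. Within chip 1 they were IRF1 0.39, MMP1 0.011, ADAMTS4 0.10, BMP7 0.17 and CDKN2B 0.26. Within chip 4, with 1 POAG array, they were the lists for melanocyte 1.02, myeloid -0.70 and antigen presentation genes -0.14, and HBG1 -0.076, HBG2 -0.14, TYROBP -0.14, AIF1 -0.50, CD14 -0.94, IFIT2 -0.55, DKK3 -0.46, SFRP2 -0.78, FRZB -1.91, TEK -0.28, GMDS -0.30, CFD 0.95 and MNDA -0.45. With the epithelium covariate KRT14 stood at 0.31 and CDKN2B at 0.83. Medians of lists also changed sign while camera's direction, relative to other genes, stayed. These were glucocorticoid 0.49, immediate early 0.31, matrix remodelling 0.57 and inflammation genes 0.28 with median scaling, glaucoma -0.48 and smooth muscle genes -0.77 with chip as a fixed block, and interferon -0.14, collagen -0.18 and Wnt genes -0.46 within chip 4. With the epithelium covariate smooth muscle stood at -1.09, and surface epithelium at 0.12 by construction. Of the named genes that passed in neither fit, MYOC turned to -0.52 with chip as a fixed block, -1.74 within chip 4 and -0.44 with the covariate, OPTN to -0.072 within chip 4, and CYP1B1 to 0.42 and VCAN to 0.15 with median scaling. Trabecular meshwork markers, also past no threshold in either fit, turned to -0.28 with chip as a fixed block. The cause was not tested. The correlation of both eyes ranged from 0.385 to 0.486 over its alternatives. For the interval limma called 0 genes under each of its alternatives. Genes near background have compressed fold changes, since detection limits their lower level.

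POAG and control titles share numbers, so the title number was also fitted as a replicate block on separate arrays. It gave 1326 genes, 773 higher and 553 lower, of which 1186 were among the 1642. Same-numbered arrays did not deviate together: over 17 shared numbers the correlations ran from -0.144 to 0.261, and 2 exceeded 0.1, so the numbers do not pair the samples.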

Other observations

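Of the tests below, those of chip, of dilution and of group labels rearranged within chips were chosen after the results they bear on were seen, as were the parting of the collagen and corneal lists and the weighing of the epithelium covariate in the dilution test, whereas those of a second epithelial gene set, of blood genes and of random splits were set before. The bound of the blood test was revised after its value was seen, as stated there.

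Matrix remodelling genes moved both ways, with 3 of 17 higher and 3 lower. The collagenase gene MMP1 stood at -1.83 ± 0.55 (SE), the stromelysin gene MMP3 at -1.92 ± 0.48 and the aggrecanase gene ADAMTS4 at -1.28 ± 0.35, and the protease inhibitor gene TIMP2 at 0.86 ± 0.16. Of 17 TGF-beta and BMP pathway genes 4 rose and 1 fell. CCN2, a matricellular growth factor gene induced by TGF-beta, rose by 1.57 ± 0.32 and TGFB3 by 1.19 ± 0.23, and BMP7 fell by 1.03. With chip as a fixed block the calls of these 3 ended, at 0.30 ± 0.83 (adjusted p = 0.926), 0.62 ± 0.49 (adjusted p = 0.623) and -0.070 ± 0.35 (adjusted p = 0.963). Antioxidant and metallothionein genes had 1 of 19 higher and 4 lower, among them MT2A (-1.24 ± 0.23) and GPX3 (-1.63 ± 0.48). Complement genes had 2 of 13 higher and 2 lower, with C5 at 1.17 ± 0.24, SERPING1 at 0.88 ± 0.26, CFD at -1.57 ± 0.26 and C3 at -1.23 ± 0.33. Hypoxia and glycolysis genes had 3 of 15 in each direction, with LDHA, a lactate dehydrogenase gene, at 0.93 ± 0.17, and ADM, the adrenomedullin gene, at -1.22 ± 0.22. Of the genes named from these 5 lists GPX3 (-3.25) and ADM (-1.69) passed with the block. The others did not, with MMP1 at -1.16, MMP3 at -1.92, ADAMTS4 at -0.95, TIMP2 at 0.98, MT2A at -1.39, C5 at 1.23, SERPING1 at 0.36, CFD at -0.93, C3 at -1.83 and LDHA at 0.70. None of these lists passed with camera (adjusted p = 0.636, 0.804, 0.215, 0.629 and 0.95), although matrix remodelling genes did with median scaling. Over each list alone the counts were the same, except 5 higher for TGF-beta and BMP, 5 lower for antioxidant and 4 lower for complement genes.

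Endothelium markers had 1 of 13 higher and 3 lower, with PLVAP, a gene of fenestrated vessels, at -1.85 ± 0.40. Smooth muscle and pericyte markers had 3 of 14 higher, with RGS5 at 1.08 ± 0.29, and ciliary epithelium markers had 1 of 7 higher, CDH2 at 1.46 ± 0.33, and 1 lower, PAX6. Inflammation genes had 2 of 13 in each direction, with CCL3 at 1.45 ± 0.39. Heat shock genes had 2 of 13 higher, oxidative phosphorylation genes 3 of 17 higher, with NDUFB8 at 1.07 ± 0.24, unfolded protein response genes 1 of 14 in each direction, proteasome genes 2 of 13, ribosomal protein genes 1 of 18 and mast cell markers 1 of 3. With limma 0 melanocyte (8 tested), Schwann cell (5), lymphoid (11), photoreceptor (3) and cell cycle (7) markers passed, against 2, 2, 1, 0 and 0 at an unadjusted p under 0.05. With the block 0 of the genes named here passed (PLVAP -1.57, RGS5 0.48, CDH2 1.65, CCL3 2.30, NDUFB8 0.92). None of these lists passed with camera. With chip as a block the endothelium (median -0.31), smooth muscle (-0.77), inflammation (-0.34) and oxidative phosphorylation (0.29) lists passed. The melanocyte list (median -0.20, adjusted p = 0.116) passed as lower in 8 of 24 other settings, among them median scaling (adjusted p = 0.00139), cyclic loess (adjusted p = 0.0115), chip as a random block (adjusted p = 0.0405) and chip 1 (adjusted p = 0.0136), and in the fits without control donor 7 (adjusted p = 0.0455) or POAG array 5 (adjusted p = 0.0376). Within chip 4, with 1 POAG array, the melanocyte median was 1.02. The endothelium median was -1.27 on that chip and -0.11 on chip 1. Its list mean differed by -1.60 on chip 4 but by 0.168 on chip 1. The POAG array of chip 4 had the lowest endothelium mean of POAG (5.54), so the endothelium fall with the block leans on that array. Outside chip 4, other passes were oxidative phosphorylation and Schwann cell within chip 1, inflammation with median scaling, and smooth muscle, heat shock and ribosomal protein lists with the epithelium covariate. The list's median, mean and test differed in sign for smooth muscle, ciliary epithelium, mast cell, unfolded protein response, hypoxia, complement, proteasome and glaucoma genes.

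Random splits of the 30 profiles into 13 and 17 were set against the real split. Of 100 splits 1, the real one, gave as many genes past the threshold (1642, highest other 25), so chance is unlikely for that count. These splits ignore chip, and 4 of the 6 chips hold 1 group. With chip as a fixed block 123 genes passed. Of the 90 arrangements of the labels within the other 2 chips 1, the real one, gave as many, the smallest share these can give. Chance is therefore unlikely for that count, although another arrangement gave 67 genes. For the lists 13 of 100 splits gave as many (9, highest other 15), so chance could not be excluded for the number of lists.

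Surface epithelium genes were lower in POAG and spread widely among control donors. A difference between chips was argued against only weakly. Within the chips that hold both groups the list mean differed by -2.19, against -2.83 over all profiles (exact p = 0.033 over 90 arrangements, adjusted p = 0.137 over the 33 lists). The difference was -2.02 in chip 1 and -2.46 in chip 4, which holds 1 POAG array. A candidate explanation is a varying share of epithelial cells in the control pieces: across 13 control donors the list mean rose with that of 14 tested epithelial genes outside it, 0 of them in another list (r = 0.909, permutation p = 2e-05, adjusted 4e-05 over 2 relations; Spearman correlation 0.912, p = 4e-05; r = 0.879 without the 2 farthest donors; r = 0.932 with exact p = 0.00694 in chip 2 and 0.866 with exact p = 0.0319 in chip 3, n = 6 each). Of those genes 7 were lower and 1 higher in POAG, with a median of -0.61. Both eyes of a donor differed in the list mean by a median of 0.44 (0.123 to 1.48 over 6 donors), and the SD over all 13 control donors was 1.72. A difference and an SD are unlike measures, and both eyes of a donor were always on different chips. Whether such cells came from dissection or were part of the tissue, and any effect of disease, stays open.

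Collagen and corneal stroma genes were higher in POAG. Dilution of control RNA by epithelial RNA was argued against as the whole cause for the corneal list, whose mean over that of endothelium, smooth muscle and melanocyte markers was higher in POAG by 1.37 (permutation p = 8e-05) and whose call stayed with the epithelium mean as a covariate (median 0.80, adjusted p = 0.00305, against 1.42 without it). The covariate fit is a weak guide, because the epithelium means of the groups overlap little. Only 4 control arrays lay within the POAG range of 5.25 to 6.49. For the collagen list dilution stays open: that difference was 0.841 (permutation p = 0.00012; 0.981 for both lists), but its median went from 0.65 to 0.07 with the covariate (adjusted p = 0.798), and the reference markers moved unevenly (-0.301, 0.018 and -0.493). A difference between chips was argued against only weakly for the corneal list (1.24 within chips, 1.15 over all profiles, exact p = 0.022, adjusted p = 0.137 over the 33 lists). The corneal difference was 0.729 in chip 1 and 2.05 in chip 4. Chip 4 holds 1 POAG array, which has the highest corneal mean of POAG (9.57). For the collagen list a difference between chips may account for the rise (0.0989 within chips, 0.623 over all profiles, exact p = 0.73). For both lists together it cannot be told apart from group (0.40 within chips, 0.764 over all profiles, exact p = 0.14), because few arrays share a chip. Disease, way of collection and the part of the meshwork taken stay open.

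Myeloid genes were higher in POAG, beside far higher red blood cell genes. A difference between chips cannot be told apart from group (0.572 within chips, 0.892 over all profiles, exact p = 0.27), with 1.30 in chip 1 and -0.593 in chip 4. Blood in the surgical pieces stays open too: 9 tested blood neutrophil and monocyte genes, 1 of them (VCAN) also in the collagen list, had a median of -0.18 with members from -1.90 (S100A12) to 1.51 (MNDA), both named after their values were seen, and 5 of them averaged under 6 (log2) in both groups, near background. Across 17 POAG arrays the myeloid mean did not rise with the red blood cell mean (r = 0.00578, permutation p = 0.982; Spearman correlation -0.0735, p = 0.783; r = -0.227 without the 2 farthest; r = -0.978 with exact p = 0.00694 in chip 5 and 0.335 with exact p = 0.576 in chip 6, where 6 arrays each were taken as independent, although on chip 5 the closely correlated arrays 6 and 11, and 8 and 10, may be repeats of 1 individual), and blood platelet genes had 2 of 7 higher. Read as first written, with any median under 0.1, or with the median plus the members' SD (0.903) under the myeloid median of 1.01, the value would have argued against blood; the requirement that it pass 0.1 by more than that SD was set after the value was seen and leaves the question undecided.

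Control array 8 lacked detection of 129 of 482 genes bright on every other control array (26.8%), against at most 0.294% on another control array. That share was computed as a test of the array and is given without an explanation. Among 136 pairs of POAG arrays, arrays 6 and 11 (r = 0.889) and arrays 8 and 10 (r = 0.536) correlated most, with the third pair at 0.383 and a median of -0.0585.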
